A study of Mus musculus with 6 samples.

How the data were processed

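RNA was measured in 6 libraries, each from the bone marrow of a separate mouse, 3 wild type (WT) and 3 with both copies of Brm inactivated (BrmKO). Brm is the older name of Smarca2. Per the labels' protocols, marrow was flushed from femurs and tibiae, lineage-positive cells were depleted, and cells that were lineage negative, c-KIT positive and SCA1 positive (LSK cells) were sorted into lysis buffer. Polyadenylated RNA was made into libraries with a SMART-Seq v4 low-input kit. That kit amplifies full-length cDNA, does not mark the strand and carries no molecular identifiers, so intervals and floors cover counting error only.

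The deposited values are whole-number read counts per Ensembl gene, not normalised, in a file per library. Per the submitters' processing notes, the tools used were bcl2fastq, FastQC, STAR, HTSeq and DESeq2, with the mouse build GRCm38. Their versions, the strand setting of the counting and the annotation release are not given in the sources used here. Each file lists the same 55487 genes and 5 rows that name no gene. Those rows were kept out of library sizes and tests. They held reads outside any gene (5.79% to 9.29% of each library), ambiguous between genes (6.23% to 6.47%), not uniquely aligned (4.38% to 5.27%), not aligned (1.99% to 2.48%) and of low quality (0.00292% to 0.00368%). HTSeq drops a read that aligns equally well to several places, so counts of genes with a near-identical copy hold only the reads that differ between the copies.

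Gene symbols, positions and biotypes came from the GENCODE M21 annotation of GRCm38, matched on the Ensembl identifier. A position was found for 55227 of the 55487 genes. Library totals ranged from 28.01 to 36.46 M reads in genes, and 27468 genes had no read in any library. With 3 reads as the floor, the level a count of 0 allows lay between 0.0828 and 0.105 CPM per library.

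The comparison was BrmKO against WT, with 3 libraries in each group and no covariate. It used edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust dispersion, TMM factors and filterByExpr, which kept 15691 genes. Adjusted p-values are Benjamini-Hochberg values over those genes, with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. Positive values are higher in BrmKO. A fold against a group with 0 reads was computed as a bound against 3 counts over the group's 3 libraries. With 1 to 3 reads in a group, the ratio is given as its 95% counting interval.

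Gene lists, 36 in all, were fixed before the data were examined, as were the tests of genes and lists, the alternatives and the naming rule. They covered chromatin remodelling subunits, stem and progenitor states, cell cycle, ribosome, mitochondria, metabolism, stress and immune responses, other cell types of the marrow, genes near Smarca2 and sex-linked genes. The list of branched-chain amino acid genes was fixed because published work on Brm and valine in blood stem cells was known. The sex-linked list was only described, and 35 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Its adjusted p is a Benjamini-Hochberg value over the 35 lists. Camera compares a list's members with all other genes. Camera with an estimated correlation and fry were alternatives. The fry p tests whether a list's genes move, on balance, in a common direction, and its mixed p whether they change in either direction. Neither sets the list against other genes.

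Genes were named by rule. Smarca2 and Smarca4 were always named. Up to 10 genes per direction were named by size of change among those that passed, with a mean of at least 5 CPM and no overlap between the groups. Placeholder names, pseudogenes, genes on the Y chromosome and those of the sex-linked list were counted and not named by this rule. Other X-linked genes could be named. Where fewer than 5 genes passed in a direction, the next by p up to 5 were described as not passing. Per list, up to 3 members with the smallest p were named, with more where members went against the rest. Some members' own results are not reported here. Any other name, such as that of a copy or its source gene, was chosen after its values were seen.

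Near-identical copies were searched with minimap2 2.31. A gene was said to have a copy where its longest transcript matched that of a non-overlapping gene at 95% identity or more over at least 50% of its length. Of the tested genes, 22 could not be searched. All libraries were compared pairwise, and no pair agreed within sampling noise (chi-square per degree of freedom 13.85 to 48.1 within groups and up to 52.4 across them).

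The tests were tried before use on simulated counts with 200 changed genes, drawn independently per gene with edgeR's dispersion estimates. In the simulation of BrmKO against WT over 15208 genes, edgeR recovered 35.9% of genes changed by 1.5-fold, 59.7% at 2-fold and 82.5% at 4-fold, and 5.08% of its calls were false. DESeq2 1.42.0, over 15685 genes, recovered 47.8%, 61.2% and 86.4%, with 19.8% false calls. Alternatives covered scaling, test, dispersion, low-count filter, replicate block, left-out libraries, gene subsets and thresholds. Figures were drawn with matplotlib 3.10.9.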

Results

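The transcriptome of LSK cells, the marrow fraction that holds blood stem cells and multipotent progenitors, was measured in 3 WT and 3 BrmKO mice. The strain background is C56Bl/6 in the labels. BRM, encoded by Smarca2, is an ATPase of the SWI/SNF chromatin remodelling complexes. The comparison asks what its loss does to gene expression in these cells. Reads in genes numbered 36.46, 33.01 and 28.01 M in WT replicates 1 to 3 and 30.35, 29.18 and 33.29 M in BrmKO replicates 1 to 3. Group means were 32.5 ± 4.25 and 30.9 ± 2.12 M (SD, n = 3, exact permutation p = 0.70, two-sided; 0.1 is the smallest p that 3 against 3 allow). All 6 libraries were from males by Ddx3y, with 2136 to 3223 reads, and Xist, with 0 to 19 reads. The first principal component held 28.9% of the variance and separated the genotypes. The second held 25% and set both replicates numbered 3 apart. Those libraries also had the highest shares of reads outside genes, 8.41% in WT and 9.29% in BrmKO, against 5.79% to 6.61% in the other 4.

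Smarca2 (ENSMUSG00000024921, chromosome 19, 26605050 to 26778322, plus strand) fell in BrmKO to 15.1% of its WT level. It had 6284, 6932 and 4270 reads in the WT libraries and 805, 761 and 958 in the BrmKO libraries, that is 179 ± 31.9 against 27.1 ± 0.691 CPM (SD, n = 3). Its log2 fold change was -2.72 ± 0.13 (edgeR, adjusted p = 2.97e-05). The count is for the gene as a whole, and where along it the remaining reads lie was not measured. Which part was removed is not given in the sources used here. Smarca4, which encodes the alternative ATPase BRG1, stood at 306 ± 40.4 CPM in WT and 331 ± 40.8 CPM in BrmKO, a log2 fold change of 0.11 ± 0.13 that did not pass (adjusted p = 0.999).

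**Figure D1:**
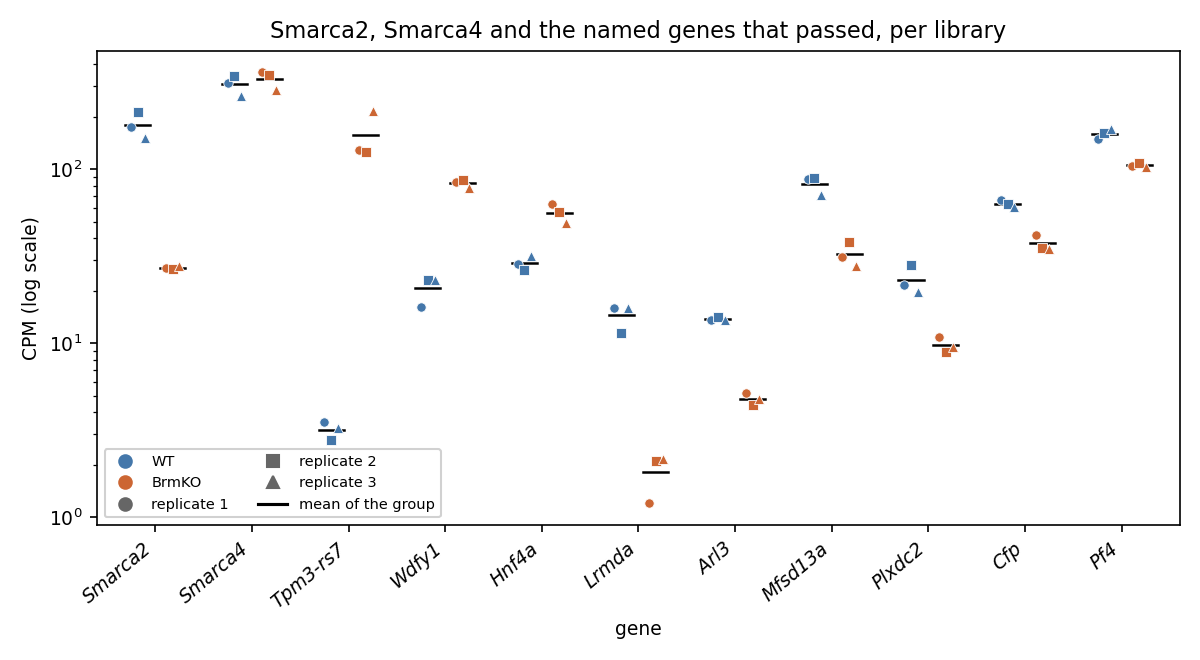
CPM on a log axis for Smarca2, Smarca4 and the named genes that passed. Symbols are the 3 WT and 3 BrmKO libraries, and bars are group means. Smarca2 lies at 26.5 to 27.9 CPM in the BrmKO libraries and at 150 to 213 CPM in WT.

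Few other genes passed. In simulation the test recovered 35.9% of genes changed by 1.5-fold and 59.7% at 2-fold, so other changes may be missed. The counts hold no sequence, so an effect of BRM cannot be told apart from other sequence differences between the mice for the genes below. Wdfy1, an endosomal FYVE-domain protein, rose from 20.7 ± 3.90 to 83.0 ± 4.24 CPM (4.01-fold, adjusted p = 0.000724). Hnf4a, a nuclear receptor best known from liver and gut, rose from 28.8 ± 2.65 to 56.3 ± 7.01 CPM (0.97 ± 0.12, adjusted p = 0.0271). Lrmda, named for a role in melanocyte differentiation, fell from 14.5 ± 2.63 to 1.82 ± 0.531 CPM (-2.99 ± 0.27, adjusted p = 0.00373). Cfp, the complement regulator properdin, fell from 63.4 ± 2.96 to 37.4 ± 4.01 CPM, and Pf4, a chemokine stored in platelet granules, fell from 159 ± 10.6 to 105 ± 3.12 CPM. In all, 22 of 15691 genes passed, 13 higher and 9 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 918 had an unadjusted p under 0.05. The groups were fully apart in 11.1% of genes, where chance gives 10%.

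Plxdc2, Arl3 and Mfsd13a were lower in BrmKO. Plxdc2, a transmembrane plexin-domain protein, fell from 23.2 ± 4.48 to 9.73 ± 0.976 CPM (adjusted p = 0.0384). Arl3, a GTPase of the primary cilium, fell from 13.7 ± 0.366 to 4.79 ± 0.362 CPM (adjusted p = 0.00916). Mfsd13a, of a transporter family, fell from 82.0 ± 9.97 to 32.4 ± 5.44 CPM (adjusted p = 0.00766). Next by p among higher genes, without passing, were Ighv1-81 (log2 fold change 3.17 ± 0.51, adjusted p = 0.0746) and Bloc1s2 (0.65 ± 0.11, adjusted p = 0.0829). Ighv1-81 passed without BrmKO replicate 3 (0.0326), while without BrmKO replicate 1, where it was highest, its log2 fold change was 2.39 (adjusted p = 0.133). Bloc1s2 passed without WT replicate 3 (0.0490). Both also passed with DESeq2 (2.85e-09 and 5.00e-05) and with no low-count filter (0.0369 and 0.00867). The number of genes that passed was 7 without WT replicate 1, 6 without WT replicate 2, 36 without WT replicate 3 and 9 without BrmKO replicate 1. Smarca2, Tpm3-rs7, Wdfy1, Lrmda and mt-Nd3 passed with any library left out, while Pf4 did not (adjusted p = 0.0564 to 0.291 over the 6 such fits). Plxdc2 was lost in all but the fit without WT replicate 3 (0.119 to 0.184) and with limma-voom (0.0597), and Cfp in the same left-out fits (0.0640 to 0.268). Without WT replicate 1, WT replicate 2, BrmKO replicate 1 or BrmKO replicate 2 the adjusted p was 0.179, 0.175, 0.132 and 0.136 for Hnf4a and 0.0729, 0.0853, 0.0563 and 0.0609 for Arl3. That of Mfsd13a was 0.0729, 0.0751 and 0.0640 in the first 3 of these.

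A second group of calls concerned genes with a near-identical copy, and their counts are uncertain. Of the 22 genes, 10 had such a copy (45.5%, against 5.87% of all tested genes searched), and 8 were pseudogenes. Tpm3-rs7, a tropomyosin 3-related sequence, rose from 3.18 ± 0.386 to 157 ± 51.9 CPM (log2 fold change 5.62 ± 0.25, adjusted p = 2.83e-05), and shares 99.1% of its bases with Tpm3. Rps3a3 and Rps3a2, processed pseudogenes chosen after their values were seen, rose from 0.511 ± 0.107 to 138 ± 70.5 CPM and from 4.64 ± 0.640 to 36.0 ± 16.8 CPM. Their source Rps3a1, a ribosomal protein gene, stood at 584 ± 59.3 CPM in WT and 253 ± 116 CPM in BrmKO, which did not pass (adjusted p = 0.682). Tpm3 likewise stood at 605 ± 51.3 and 409 ± 102 CPM (adjusted p = 0.546). The mitochondrial mt-Nd3 fell from 252 reads over the WT libraries to 1 (95% counting interval of the ratio 42.9 to 9565), while Gm28438, a nuclear copy on chromosome 1 with 100% identity over 99.1% of its length, rose from 1 read to 285. Without genes that have a copy, a count chosen after seeing the data, 12 genes passed, 5 higher and 7 lower.

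**Figure D2:**
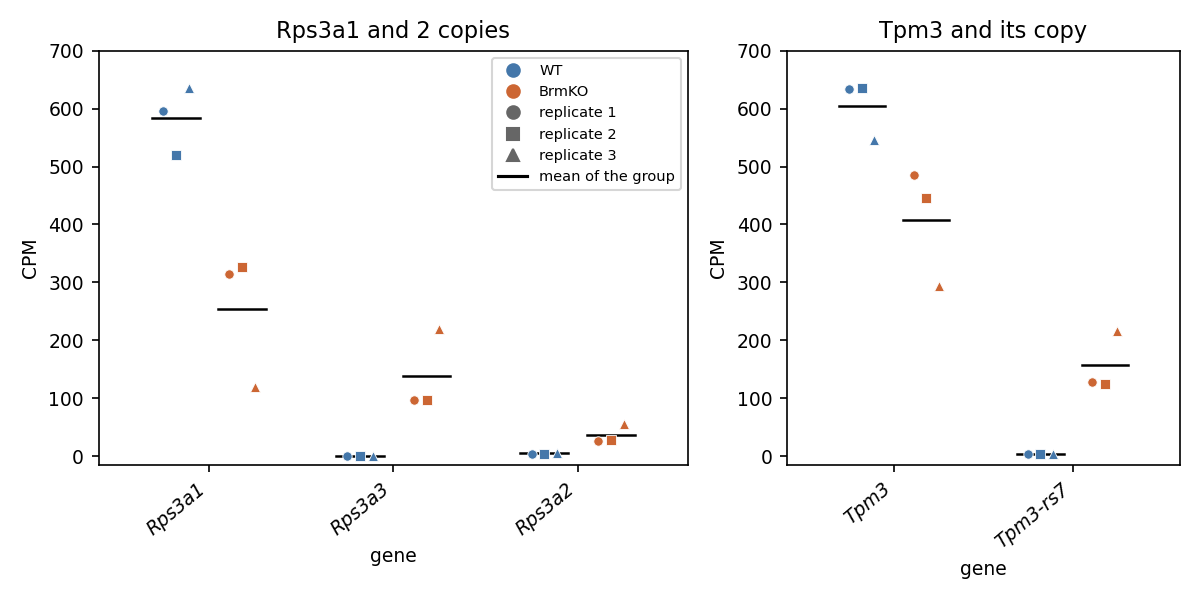
CPM per library of Rps3a1 with its copies Rps3a3 and Rps3a2, and of Tpm3 with its copy Tpm3-rs7, on linear axes. Symbols are libraries and bars are group means. Rps3a1 is at 314 and 326 CPM in BrmKO replicates 1 and 2 and at 120 CPM in BrmKO replicate 3, where Rps3a3 is highest at 219 CPM.

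Smarca2, Mfsd13a, Arl3 and Pkd2l1 all lie on chromosome 19. Pkd2l1, a polycystin channel gene chosen after its values were seen, had 0 reads in WT and 139 in BrmKO, so it was at least 48.4-fold higher in BrmKO. Of 540 tested genes of chromosome 19 other than Smarca2, 12 had an unadjusted p under 0.001, against 60 of 15134 elsewhere (two-sided Fisher's exact test, p = 5.77e-06). Most of the 12 lie near each other and are not separate cases, so that p may be too small. This comparison of chromosome 19 with the rest was not among the tests fixed beforehand. They started between 11.78 and 56.32 Mb, and 0 of the 95 tested genes within 10 Mb of Smarca2 were among them. In the fixed list of Smarca2 neighbours, 0 of 19 measured genes passed over all genes and 0 adjusted over the list alone (3 had an unadjusted p under 0.05; camera adjusted p = 0.119). Vldlr, Ric1 and Ranbp6 had its smallest p, with log2 fold changes of 0.52 ± 0.18, -0.41 ± 0.14 and -0.40 ± 0.15.

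**Figure D3:**
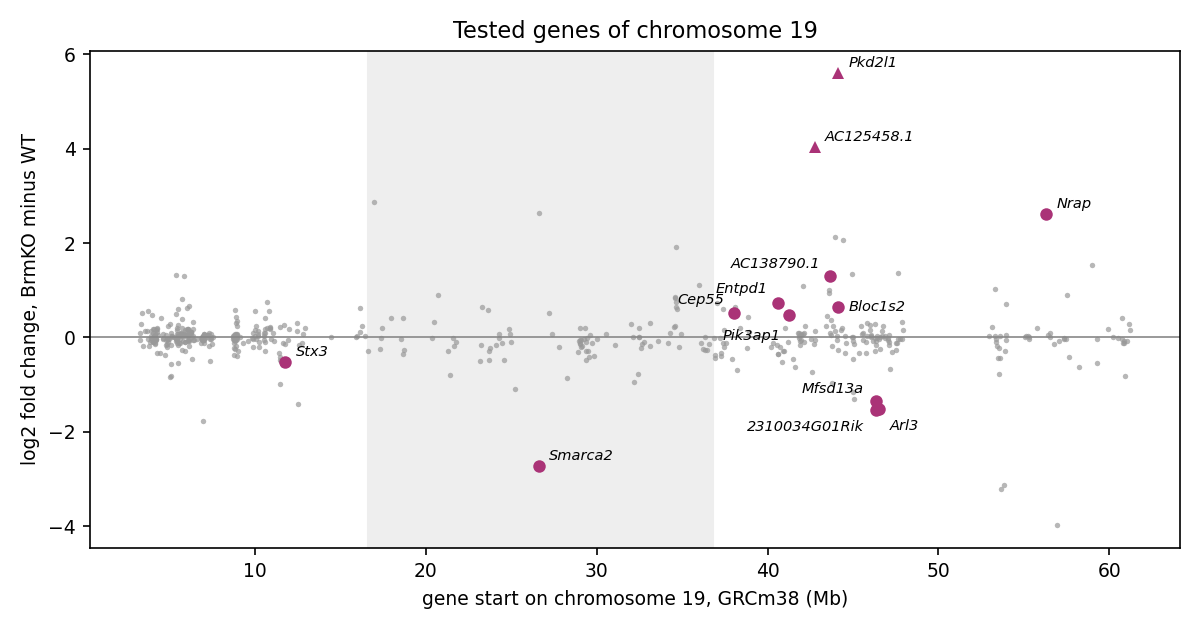
Log2 fold change of each tested gene of chromosome 19 against its start in GRCm38 (Mb). Named points have an unadjusted p under 0.001, triangles are lower bounds for genes with 0 reads in WT, and the grey band spans 10 Mb on either side of Smarca2. Most named points other than Smarca2 lie between Cep55 at 38055011 and Arl3 at 46531096.

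Gene lists were then examined for members that moved together. Interferon-stimulated genes ranked higher in BrmKO. Of 36 measured, 34 had a log2 fold change above 0, with a median of 0.25 (camera adjusted p = 2.93e-09, and adjusted p = 0.53 with an estimated correlation). None of them passed over all genes in edgeR, 8 had an unadjusted p under 0.05, and 1, Irf7, passed adjusted over the list alone, at 44.2 ± 3.26 CPM in WT and 60.8 ± 2.70 in BrmKO. Ifit1 had a log2 fold change of 0.76 ± 0.23 and Isg15 of 0.67 ± 0.21, whereas Herc6 and Parp14 had -0.09 ± 0.20 and -0.07 ± 0.22. WT replicate 1 lay lowest, at a list mean of -0.39 from the mean of all libraries against -0.04 and -0.07 in the other WT libraries, and the median was 0.17 without it. This list also passed in 5 of the other 9 splits of the 6 libraries into 3 and 3, each of which still divided the genotypes unevenly. MHC class I and peptide loading genes lay above 0 in 17 of 18 (median 0.13, camera adjusted p = 0.00435, and adjusted p = 0.81 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. H2-T22, Nlrc5 and Tap1 had its smallest p, with log2 fold changes of 0.26 ± 0.10, 0.32 ± 0.14 and 0.23 ± 0.11. The class I call was lost without WT replicate 1, WT replicate 2 or BrmKO replicate 2 (adjusted p = 0.0885, 0.0688 and 0.0702).

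Dendritic cell and MHC class II genes also ranked higher, 11 of 14 above 0 with a median of 0.49 (camera adjusted p = 0.000102, and adjusted p = 0.53 with an estimated correlation). H2-Ab1 stood at 133 ± 74.7 CPM in WT and 303 ± 69.3 in BrmKO, and Cd74, the invariant chain, at 121 ± 66.3 and 275 ± 70.4. H2-Oa had a log2 fold change of 0.42 ± 0.17. Siglech, Ly6d and Itgax, markers outside MHC class II, went the other way, at -0.34 ± 1.09, -0.26 ± 0.26 and -0.11 ± 0.28. None of the 14 passed over all genes and 0 adjusted over the list alone, while 6 had an unadjusted p under 0.05.

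**Figure D4:**
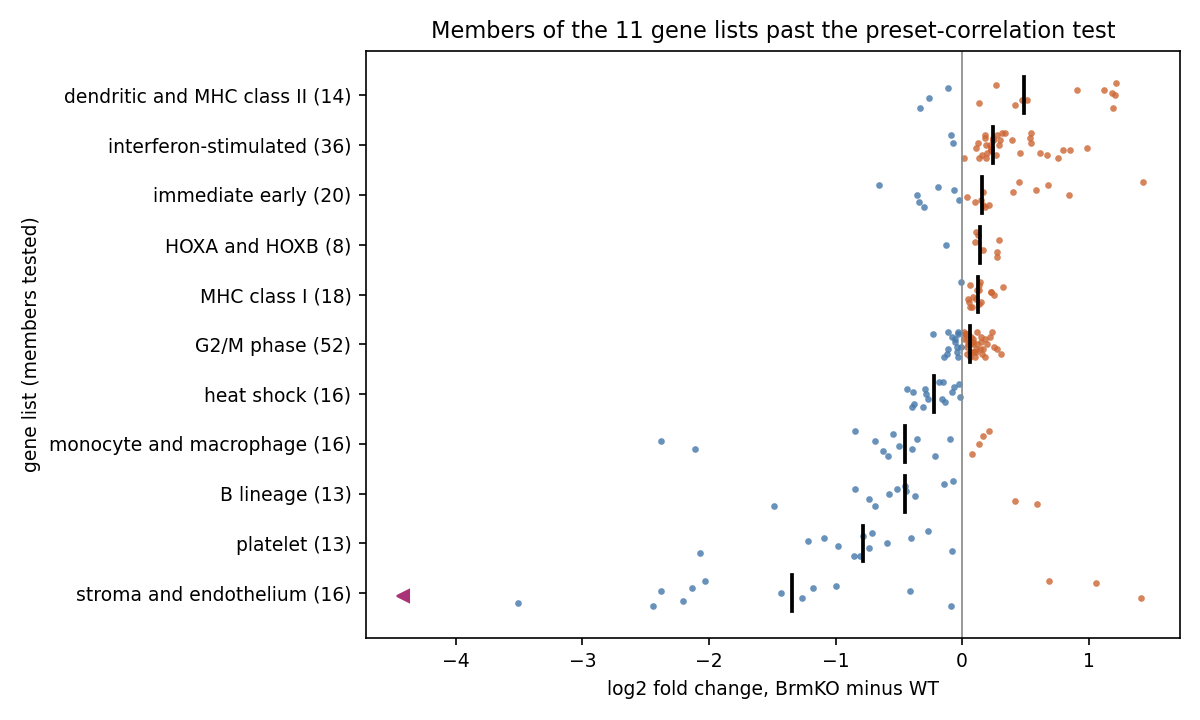
Log2 fold change, BrmKO minus WT, of each measured member of the 11 lists past the camera test with the preset correlation. Points are genes, black bars are list medians, and the triangle is a bound for Pdgfra, which has 0 reads in BrmKO. All 13 platelet genes and all 16 heat shock genes lie below 0.

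Platelet and megakaryocyte genes ranked lower in BrmKO, with all 13 below 0 and a median of -0.78 (camera adjusted p = 1.31e-06, and adjusted p = 0.53 with an estimated correlation). The median was -0.40 without WT replicate 3, where these genes lay highest. Pf4 fell over all genes, and 4 passed adjusted over the list alone. These were Pf4, Treml1 with a log2 fold change of -0.81 ± 0.17, Selp at 32.1 ± 7.45 CPM in WT and 18.7 ± 2.62 in BrmKO, and Itgb3 at 67.0 ± 17.8 and 40.9 ± 4.83. Megakaryocyte and erythroid progenitor genes did not pass (17 measured, median -0.01, camera adjusted p = 0.405), except without BrmKO replicate 2 (0.00240), although Pf4 is a member and alone passed adjusted over the list alone. Gp5 and Tfrc followed with log2 fold changes of -0.38 ± 0.17 and -0.16 ± 0.09.

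Stromal, bone and endothelial markers, which the LSK gate should leave out, ranked lower in BrmKO, 13 of 16 below 0 with a median of -1.35 (camera adjusted p = 3.16e-06, and adjusted p = 0.53 with an estimated correlation). None passed over all genes in edgeR, 7 had an unadjusted p under 0.05, and 5 passed adjusted over the list alone. Pdgfra had 67 reads in WT and 0 in BrmKO, at least 21.4-fold lower, Kdr stood at 16.9 ± 9.26 and 6.27 ± 1.58 CPM, and Plvap had a log2 fold change of -1.18 ± 0.31. Lepr and Lpl followed at -3.51 ± 1.06 and -0.99 ± 0.33. The bone collagen genes Col1a1 and Col1a2 lay above 0 (1.41 ± 1.68 and 0.68 ± 1.30), as did Dcn (1.05 ± 0.90). The list median was -0.70 without WT replicate 1 and -2.11 without BrmKO replicate 3. Set against the mean of all libraries, the list mean was 1.78, 0.20 and -0.08 in WT and -0.69, -1.59 and 0.38 in BrmKO. The genotypes thus overlapped, with BrmKO replicate 3 above WT replicates 2 and 3.

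B lineage markers lay below 0 in 11 of 13 (median -0.45, camera adjusted p = 0.0162, and adjusted p = 0.53 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. Ighm and Cd79a had log2 fold changes of -0.58 ± 0.25 and -0.74 ± 0.36, and Igkc and Fcrla went the other way at 0.59 ± 0.56 and 0.42 ± 0.68. Monocyte and macrophage markers lay below 0 in 12 of 16 (median -0.45, camera adjusted p = 0.0190, and adjusted p = 0.53 with an estimated correlation). None of these passed over all genes, and 1, Ccr2, passed adjusted over the list alone, with a log2 fold change of -0.63 ± 0.16. Vcam1 had a log2 fold change of -2.38 ± 0.92, while C1qb, Ctss, Cd163 and Cd68 lay above 0. The B lineage call was lost without WT replicate 1, BrmKO replicate 1 or BrmKO replicate 2 (adjusted p = 0.0880, 0.0878 and 0.0702), and the monocyte call without WT replicate 1 or BrmKO replicate 2 (0.0885 and 0.0702).

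Lists that can follow tissue handling ranked in opposite directions, though the libraries of the genotypes overlapped. Set against the mean of all libraries, the heat shock mean was -0.14, 0.12 and 0.27 in WT and -0.16, -0.06 and -0.03 in BrmKO. That of the immediate early genes was 0.03, 0.40 and -0.78 in WT and 0.51, 0.12 and -0.29 in BrmKO, lowest in replicate 3 of either genotype. Heat shock genes lay below 0 in 16 of 16 (median -0.22, camera adjusted p = 0.0205, and adjusted p = 0.53 with an estimated correlation), with 0 past the threshold over all genes. Hsph1 alone passed adjusted over the list alone, at 238 ± 20.2 CPM in WT and 182 ± 12.9 in BrmKO, and Chordc1 and Hspa8 had log2 fold changes of -0.29 ± 0.10 and -0.40 ± 0.15. Immediate early genes lay above 0 in 13 of 20 (median 0.16, camera adjusted p = 0.0217, and adjusted p = 0.92 with an estimated correlation), with 0 past the threshold over all genes. Klf4 passed adjusted over the list alone, at 12.4 ± 4.49 CPM in WT and 33.3 ± 10.7 in BrmKO, Dusp1 and Fos had log2 fold changes of 0.59 ± 0.18 and 0.67 ± 0.23, and Nr4a1 went against them at -0.66 ± 1.40. The immediate early call was lost without WT replicate 1, WT replicate 3, BrmKO replicate 1 or BrmKO replicate 2 (adjusted p = 0.0880, 0.829, 0.356 and 0.0702). The heat shock call was lost without WT replicate 2, WT replicate 3, BrmKO replicate 1 or BrmKO replicate 3 (0.106, 0.0730, 0.0595 and 0.0728).

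G2/M phase genes lay above 0 in 38 of 52 by a small margin (median 0.06, camera adjusted p = 0.0306, and adjusted p = 0.91 with an estimated correlation). Ect2 and Plk1 had log2 fold changes of 0.27 ± 0.08 and 0.31 ± 0.13, and Cbx5 of -0.23 ± 0.09. HOXA and HOXB genes lay above 0 in 7 of 8 (median 0.14, camera adjusted p = 0.0306, and adjusted p = 0.53 with an estimated correlation), led by Hoxa9 and Hoxa10 at 0.27 ± 0.09 and 0.28 ± 0.15, with Hoxb5 at -0.13 ± 0.57. Without WT replicate 3, BrmKO replicate 1 or BrmKO replicate 2 the G2/M adjusted p was 0.339, 0.221 and 0.555, and without WT replicate 2, WT replicate 3 or BrmKO replicate 1 the HOX adjusted p was 0.0535, 0.219 and 0.356. The HOX call was also lost with voom weights (0.0722) and the G2/M call with no low-count filter (0.117). In both lists 0 passed over all genes and 0 adjusted over the list alone. In all, 11 of 35 lists passed camera with the preset correlation, 6 higher and 5 lower, and 0 passed with an estimated correlation or with the fry p (2 had an unadjusted p under 0.05 with an estimated correlation). Without WT replicate 1, 7 lists passed, and without BrmKO replicate 1, 6 passed. The fry mixed p passed for 4 lists, those of stromal and endothelial, mitochondrially encoded, platelet, and T and NK cell genes (adjusted p = 0.000135, 0.000289, 0.0144 and 0.0144). In the mitochondrially encoded list mt-Nd3, whose counts are uncertain, was the only member with an unadjusted p under 0.05.

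Stem and progenitor programmes did not pass. The 30 haematopoietic stem cell genes had a median log2 fold change of -0.01 (camera adjusted p = 0.988), with Hoxa9 and Hlf above 0 (0.27 ± 0.09 and 0.39 ± 0.14) and Ctnnal1, Sult1a1 and Tek below it. Lymphoid-primed progenitor genes had a median of -0.05 (17 genes, adjusted p = 0.253), with Il7r at 15.1 ± 2.36 CPM in WT and 9.20 ± 1.68 in BrmKO. Myeloid progenitor genes had a median of 0.01 (18 genes, adjusted p = 0.937), quiescence genes 0.02 (19 genes, adjusted p = 0.253) and G1/S genes 0.04 (44 genes, adjusted p = 0.252). The other SWI/SNF subunits had a median of 0.03 (26 genes, adjusted p = 0.487), with Ss18l1 at -0.38 ± 0.15 and Smarcd3 at 1.16 ± 0.47. In these lists 0 members passed over all genes in edgeR and 0 adjusted over the list alone.

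Metabolic and biosynthetic lists did not pass either. Branched-chain amino acid catabolism genes had a median of 0.04 (26 genes, camera adjusted p = 0.664), amino acid transport and sensing genes -0.01 (26 genes, 0.937) and ATF4 response genes 0.01 (21 genes, 0.755). Slc43a1, a transporter of branched-chain amino acids, had a log2 fold change of 0.27 ± 0.09 and Slc43a2 of -0.23 ± 0.09. Ribosome biogenesis genes had a median of -0.07 (22 genes, adjusted p = 0.215), ribosomal proteins -0.01 (77 genes, 0.977), nuclear oxidative phosphorylation genes -0.04 (75 genes, 0.405), and glycolysis and hypoxia genes 0.02 (29 genes, 0.544). In these lists 0 members passed over all genes and 0 adjusted over the list alone. Mitochondrially encoded mRNAs had a median of -0.14 (10 genes, adjusted p = 0.102), with mt-Nd3 alone past the threshold, over all genes and adjusted over the list alone. That list passed without WT replicate 2 or BrmKO replicate 3 (0.00265 and 0.00191), as did oxidative phosphorylation (0.00135 and 0.0315). Ribosome biogenesis passed without WT replicate 3 or BrmKO replicate 2 (0.00774 and 0.0375), and ribosomal proteins without WT replicate 2 or WT replicate 3 (0.0224 and 0.0268), in opposite directions. The mean log2 level of the mitochondrially encoded mRNAs, set against the mean of all libraries, was 0.24, -0.06 and 0.70 in the WT libraries and -0.50, -0.48 and 0.10 in the BrmKO libraries, so it was highest in replicate 3 of either genotype.

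Of the remaining signalling lists, NF-kB and inflammatory genes had a median of -0.08 (18 genes, camera adjusted p = 0.931), p53 targets -0.05 (21 genes, 0.878), BCL2 family genes -0.07 (14 genes, 0.988) and TGF-beta and BMP genes -0.01 (20 genes, 0.798). None of their members passed over all genes or adjusted over the list alone, with Bok (0.85 ± 0.26) and Phlda3 (0.73 ± 0.22) among the smallest p. Among other cell types, maturing erythroid markers had a median of -0.08 (12 genes, adjusted p = 0.681) and granulocyte markers of -0.28 (12 genes, 0.253), with 0 past either threshold. The erythroid list passed without WT replicate 3 (0.0237) and the granulocyte list without WT replicate 2 or BrmKO replicate 3 (0.0354 and 0.0380). T and NK cell markers had a median of 0.23 (15 genes, 0.242) and went both ways adjusted over the list alone, where Ncr1 was higher (2.22 ± 0.55) and Trbc1 lower (-0.86 ± 0.21). Mast cell, basophil and eosinophil markers had a median of 0.29 (14 genes, 0.544), and Cpa3 passed adjusted over the list alone, at 129 ± 6.81 CPM in WT and 82.9 ± 17.4 in BrmKO.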

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

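The fits with the share of reads outside genes, without both libraries numbered 3 and without genes that have a copy were chosen after seeing the data. Against 22 genes (13 higher, 9 lower), DESeq2 called 141 (88 and 53), voom with quality weights 47 (33 and 14), no low-count filter 58 (40 and 18), the share of reads outside genes as a covariate 47 (33 and 14), a threshold of 0.1 36 (25 higher), and the fit without copies 12 (5 higher). The cause was not tested, except that the last drops genes by construction and the threshold of 0.1 is looser. DESeq2 ran with its own filter on 27976 genes, so test and filter changed together. It made 19.8% false calls in simulation, over 15685 genes with dispersions estimated by edgeR, so that share need not hold here. All 22 genes were among the calls of DESeq2 and of the covariate fit. Without both libraries numbered 3, 18 genes passed, 10 of them among the 22, and 8 lists. Arl3, Plxdc2, Cfp and Pf4 (adjusted p = 0.0620, 0.0684, 0.07002 and 0.0684) and the immediate early, heat shock and HOX lists (0.324, 0.0922 and 0.188) were lost there. The mitochondrially encoded list passed with voom weights, the CPM filter and the covariate (0.0479, 0.00974 and 0.0454). With 1 library left out, the counts ranged from 6 to 36 in all, 2 to 22 higher and 3 to 14 lower, and lists from 6 to 13. Lists numbered 0 with an estimated correlation and 0 with fry. The ribosomal protein list turned to a pass in the lower direction without WT replicate 2 (adjusted p = 0.0224), and passed in the higher direction without WT replicate 3 (0.0268), against 0.830, 0.356, 0.743 and 0.0704 without WT replicate 1 and BrmKO replicates 1 to 3. The cause was not tested. Smarca2 passed under all 18 alternatives, from -2.85 to -2.58, and the 22 calls kept their sign wherever tested. Calls lost without a named library were those of Hnf4a (WT replicates 1 and 2, BrmKO replicates 1 and 2, adjusted p = 0.132 to 0.179), Arl3 (the same 4, 0.0563 to 0.0853), Mfsd13a (WT replicates 1 and 2, BrmKO replicate 1, 0.0640 to 0.0751), Cfp and Plxdc2 (all but WT replicate 3, 0.0640 to 0.268), and Pf4 (all 6, 0.0564 to 0.291). The titles' numbers 1 to 3 were not taken to pair the mice: deviations from the group means correlated at 0.05, 0.01 and 0.19 across genes, so the libraries numbered 3 resembled each other while WT replicate 2 correlated best with BrmKO replicate 1. A replicate block gave 25 genes, 15 higher and 10 lower, of which 17 were shared, and 10 lists. Plxdc2 (adjusted p = 0.0539) and the HOX list (0.0716) were lost with that block, and Bloc1s2 passed (0.0251), as it did with quality weights (0.0316) and the covariate (0.0131). Depth limits genes near the floor of 0.0828 to 0.105 CPM, where a count of 0 is not absence.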

Other observations

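Some genes outside the fixed lists moved beside each other on the chromosome, without passing over all genes unless said. Names here were chosen after their values were seen. Cd1d2, Selenbp2, Pi4kb, Tmod4 and Polr3gl, all between 86986551 and 96594181 on chromosome 3, had log2 fold changes of 1.65, 4.24, 1.09, 2.69 and 0.81, and 1500004A13Rik in the same stretch had -1.62. On chromosome 13, the histone gene Hist1h4m fell (-2.13, adjusted p = 0.0228) while its near-identical neighbour Hist1h4n stood at 3.17 CPM in WT and 8.45 in BrmKO. On chromosome 14, Gm47601 rose and Lrmda, in which it lies, fell (adjusted p = 0.0123 and 0.00373). Outside chromosome 19, 14 genes with an unadjusted p under 0.001 lay within 2 Mb of another, against a mean of 9.34 in 10000 random sets of as many genes (permutation p = 0.142), and the highest of the other splits had 15. Y-linked Eif2s3y, Kdm5d and Ddx3y had log2 fold changes of -0.52, -0.51 and -0.25 and passed adjusted over the list alone.

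The counts were set against other splits of the 6 libraries. Of the tests in this part, those of the other splits of all calls and of chromosome 19 in other splits were planned before their results were seen, and the others were chosen after. The real split gave 22 genes and the highest of the other 9 gave 2, with 1 of the 10 splits reaching 22. It gave 11 lists, the highest of the others gave 13, and 4 of the 10 splits reached 11. With 10 splits no share under 0.05 can be had.

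Chromosome 19 held more genes with an unadjusted p under 0.001 than its size gives. That count was 12 of 540, without Smarca2. In the other splits the highest count was 2 against 12. Over all chromosomes, 72 genes reached that p in the real split. The other splits had 62, 51 and, in the rest, 2 to 8. Only the splits with 62 and 51 could have held 12 on chromosome 19, and each held 2. The rest had too few genes to show such an excess. Neighbours that vary together and fall along the genotype split by chance would not show there, so that explanation stays open. Sequence of another strain kept around the targeted allele cannot be told apart from an effect of BRM on these genes, since the counts hold no sequence: genes within 10 Mb of Smarca2 numbered 0 of 95 and the rest 12 of 445 (two-sided Fisher's exact p = 0.138). It may account for Mfsd13a, Arl3 and Pkd2l1 as a hypothesis, and an effect of BRM loss stays open, untested.

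Genes with a near-identical copy made up 10 of the 22 calls, more than among other tested genes (Fisher's exact p = 1.55e-07). The 10 are not separate cases, so that p may be too small. Of them, mt-Nd3 and Gm28438 are copies of each other, and Rps3a3 and Rps3a2 share the source Rps3a1. Reads placed on another copy because of a sequence variant are a candidate explanation for the copies of chromosome 3 genes. There, Rps3a1 lost 1.96 times and Tpm3 1.28 times the CPM that their called copies gained. Of the 331 CPM that Rps3a1 lost, its called copies gained 168, so the rest is not matched by them. Outside chromosome 3, mt-Nd3 lost 0.874 times and Paox 4.94 times what their copies gained, so most of the Paox loss is not matched by its copy. The 2.61 CPM that mt-Nd3 lost fell short of the 2.98 CPM that Gm28438 gained by less than its WT SD of 0.701. Reads placed on another copy are thus a candidate there too, though the counts hold no sequence to test it. Mid1, Hmgn1 and Npm3 had too few reads or too small a gain for such a test, so the explanation stays open for them. Genes with an unadjusted p under 0.001 that lie on chromosome 3, or are copies of genes there, moved further in BrmKO replicate 3 than in the other BrmKO libraries in 10 of 11 cases, Ccn1 being the exception at a ratio of 0.953, and 8 of 11 passed a ratio of 1.5, against 12 of 62 others. The 11 are not separate cases, since Rps3a3 and Rps3a2 share a source and most of the others lie near each other, so the p that follows may be too small. The median ratio was 2.27 over 11 genes against 1.04 over 62 others (permutation p = 9e-05, two-sided, 100000 resamples), which may reflect a chromosome 3 segment of another strain at a different dose in that mouse, a hypothesis found and tested on the same data.

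The lists of interferon-stimulated genes and of dendritic cell and MHC class II genes ranked higher in BrmKO in camera with the preset correlation (adjusted p = 0.53 for either list with an estimated correlation). Linkage of the 3 members on chromosome 19, Ifit genes, to Smarca2 is argued against as the source of the whole list's shift. Without them the other 33 kept a median of 0.24 (camera adjusted p = 4.42e-08, with the preset correlation). Whether linkage bears on those 3 genes themselves stays open. The list passed in 5 of the other 9 splits, so these genes may vary together between mice of either genotype. Each of the 9 still divided the genotypes unevenly, so a genotype difference could also make the list pass there. The count cannot tell these apart. Dendritic cells carried past the lineage, c-KIT and SCA1 gate cannot be told apart from a change in the LSK cells: 8 MHC class II genes had a median of 1.16 and 6 other dendritic markers 0.18, of which 3 lay above 0, and their low levels leave a small share of such cells open. An effect of BRM loss also stays open.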
